A study of Mus musculus with 12 samples.

How the data were processed

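RNA sequencing was done on neutrophils from the blood of female mice. According to the labels, wild-type (WT) mice and mice of a line named Hmgb1ΔMye received saline or lipopolysaccharide (LPS, a bacterial outer membrane component that activates Toll-like receptor 4) at 0.5 mg/kg for 16 hours, and neutrophils were then isolated. The name ΔMye is used for a deletion in myeloid cells. There were 4 groups of 3 libraries, 12 in all: WT-Saline, WT-LPS, KO-Saline and KO-LPS, where KO stands for the Hmgb1ΔMye label. Per the labels' protocols, total RNA was purified with the miRNeasy micro kit (Qiagen) and libraries were made with the Universal Plus Total RNA kit with mouse probes (Tecan), a kit that marks the strand of origin. The labels do not say that the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

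The authors deposited a table of normalized expression for 9374 genes listed by NCBI Gene ID. Its values are on a log2 scale. The deposited log2 values were found to have the form log2 CPM (reads scaled to a common library size), with 0.5 added to the reads, the form that limma's voom gives, because whole reads came back within 0.0001 for 100.0% of the values in each of the 12 columns. The scaling factors ran from 0.938 to 1.044 with a geometric mean of 1.0. Per the submitters' processing notes, the genome build was mm10. The aligner, the read counter, its annotation, its strand setting and the filter on genes are not given in the sources used here. In the table every gene had at least 8 reads in total and reads in at least 4 libraries. All 12 columns were used.

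The recovered reads gave the depth. The libraries held 399702 to 526757 reads in the table, 5347060 in all. The median gene had 11.33 reads per library, and 6.93% to 19.19% of genes had 0 reads in a library. A count of 0 reads allowed up to 5.58 to 8.00 CPM, taking a floor of 3 reads per library. Reads without molecular identifiers are not independent molecules, so the 95% intervals and floors given here cover counting error only. Gene symbols were found for 9372 IDs. Of the genes, 9299 were matched to the mm10 gene annotation GENCODE M21. By their RefSeq gene type, the 9374 genes included 8691 protein-coding genes and 537 long non-coding RNAs. Coordinates are 1-based and in mm10. Exons of 3419 matched genes (36.8%) overlapped exons of a gene on the opposite strand by at least 1 base, and 5880 had no such overlap. The strand setting of the counting being unstated, values of overlapping genes are uncertain, may be those of the gene on the other strand, and are marked as such. Genes whose annotated spans overlap on the same strand, and members of gene families or genes with pseudogene copies, carry the same uncertainty. Had the reads been counted with the opposite strand setting, which is taken up below, the doubt would cover all genes, Hmgb1 included, and the read depth.

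The deposited log2 values were tested as they stood with limma: a linear model of the 4 group means over all 12 libraries, which share 1 estimate of the spread per gene, and moderated statistics with a mean-variance trend. Tests were two-sided and a gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each comparison, over all 9374 genes. The design had allowed for a minimum of 1 in at least 3 libraries, which removed no gene. The comparisons were LPS against saline in WT and in KO-labelled libraries, KO-labelled against WT libraries in saline, in LPS and averaged over both treatments, and the interaction, which is the LPS response of KO-labelled libraries minus that of WT libraries. Adjusted p-values in the text are from this limma model unless another test is named, and ± after a log2 fold change is its standard error. Fitted fold changes are on the log2 scale with 0.5 reads added, which understates changes of low genes. Where a group had 0 reads in all 3 libraries, the fold change is given as a bound against the floor of 3 reads per library, and where it had 1 to 3 reads, as the ratio of pooled reads with its 95% counting interval.

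The named genes were chosen by a rule set before the data were examined, as were the comparisons, the gene lists and most of the alternative analyses. Hmgb1 came first. For each of the 4 pairwise comparisons, the rule took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher group mean was at or above the median, passing over predicted genes, pseudogenes and antigen receptor segments. For the averaged difference and the interaction it took the 5 largest each way, without the condition on overlap of the groups. From each list it took up to 4 called members with the largest change, or up to 2 of the most abundant members where none was called. Where fewer than 10 genes were called, all of these and the 5 of smallest p were named. Further list members are given only as counts, and some genes that the rule took are not reported here.

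The 26 gene lists were 18 of pathways and 8 of cell type markers, holding 596 genes of which 437 were measured. The pathway lists covered interferon-stimulated genes, NF-kB targets with cytokines and chemokines, azurophil granule, specific granule, and gelatinase and secretory vesicle genes, adhesion and chemoattractant receptors, NADPH oxidase and antioxidant genes, Toll-like receptor and HMGB1 receptor signalling, high-mobility group genes, autophagy, inflammasome and cell death genes, apoptosis, cell cycle, immediate-early and MAP kinase genes, glycolysis, oxidative phosphorylation, heat shock and unfolded protein response, and lipid mediators. The markers were of mature neutrophils, monocytes and macrophages, dendritic cells, T and NK cells, B cells, platelets, erythroid cells, and eosinophils, basophils and mast cells. The 23 lists with at least 5 measured genes were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Some genes stand in more than 1 list. No direction is given for lists that did not pass, because the mean, the median and the test of several of them differed in sign. The list level of a library is the mean log2 value of its measured members. Differences of list levels were tested with a two-sided exact permutation test, for which 3 libraries against 3 cannot give a p under 0.1.

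The alternatives were pseudocounts of 0.1 and 5 on the recovered CPM, a minimum mean of 10, quantile normalization, median-ratio rescaling, no trend, the replicate number as a block, array weights, the 2 compared groups alone, a fold threshold of 2, leaving out each library in turn, and for lists an estimated correlation and the rotation test fry. Voom weights on the recovered reads, the genes without opposite-strand overlap, and leaving out libraries for the list tests, the list levels, Hmgb1 and the comparison of the LPS responses were added after seeing the data. Groupings of the libraries other than the real ones were refitted, all 10 for 3 libraries against 3 and 100 of 200 for 6 against 6. The fit was tested on simulated data for LPS against saline in WT with 9374 genes of which 200 were changed. Counts were drawn independently for each gene with a dispersion fixed at 0.1, which was not estimated from the data. Over 5 draws the fit recovered 1.4% of genes changed 2-fold and 50.8% of those changed 4-fold, and 1.4% of its calls were false. These rates hold for the simulated setting and may differ in the real libraries. The work used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, pyranges 0.1.4 and matplotlib 3.10.9.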

Results

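Expression of 9374 genes was measured in blood neutrophils of WT and Hmgb1ΔMye mice 16 hours after saline or 0.5 mg/kg LPS, with 3 libraries in each of the 4 groups. Depth was low, from 399702 reads in the table for KO-Saline replicate 1 to 526757 for WT-Saline replicate 3. Several known neutrophil transcripts were abundant, others not. S100a9, a calprotectin subunit, ranked 11 by mean reads, Csf3r, the G-CSF receptor, 14, S100a8 24 and the gelatinase Mmp9 25, while among the 14 mature neutrophil markers Clec4d ranked 817, Cxcr4 880, Acod1 978, G0s2 1822 and Ly6g, with 27.2 reads per library, 2853. Of the 50 genes with the most reads, 32 overlapped exons on the opposite strand. The first of them, Ddx39a, had 11344.3 reads per library against 687.5 for its overlapping neighbour Adgre5. Among 224 long non-coding RNAs that overlapped a measured protein-coding gene on the other strand, 168 (75%, 95% exact binomial interval 68.8% to 80.5%) had more reads than that gene. Counting with the opposite strand setting, taken up below, would give this. It would put all values in doubt, also those of genes without overlap.

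Hmgb1, the targeted gene, encodes a chromatin protein that also acts as an alarm signal outside cells. It lies on the minus strand of chromosome 5 (149046702 to 149184489), and its exons overlap those of Uspl1 by 42 bases. Hmgb1 reads were not lower in the libraries labelled KO. They were 8, 17 and 12 in WT-Saline, 14, 15 and 34 in WT-LPS, 14, 10 and 25 in KO-Saline, and 6, 30 and 16 in KO-LPS, replicates 1 to 3 in each. The level in CPM (reads scaled to a common library size) was 25.9 ± 8.83 in WT-Saline, 42.7 ± 17.8 in WT-LPS, 39.7 ± 19.7 in KO-Saline and 41.4 ± 29.7 in KO-LPS (SD, n = 3). Pooled, 100 reads in the 6 WT libraries stood against 101 in the 6 KO-labelled libraries, a ratio of 1.15 with a 95% counting interval of 0.867 to 1.54. The averaged log2 difference was 0.16 ± 0.40 (adjusted p = 0.978), with 0.53 ± 0.57 in saline (adjusted p = 0.915) and -0.21 ± 0.57 in LPS (adjusted p = 0.992). The values count reads over the whole gene, which may include exons outside the deleted part and reads of its processed pseudogenes, so they do not check the genotype labels. The libraries are therefore called KO-labelled throughout, and every direction between genotypes rests on the labels.

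**Figure D1:**
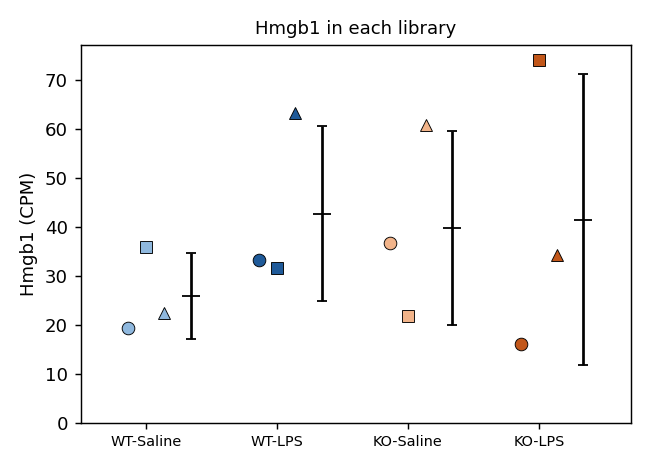
Hmgb1 in CPM (vertical axis) in each library of the 4 groups (horizontal axis), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). The KO-labelled libraries lie between 16.0 and 74.0 CPM and the WT libraries between 19.4 and 63.2.

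The first comparison asked how neutrophils isolated from WT mice differed after LPS. The mice received the LPS, so a changed mix of cells in the samples cannot be told apart from a response within cells. Rises, falls and responses, here and below, cover both. LPS raised 23 of 38 interferon-stimulated genes and 13 of 18 genes of the neutrophil's specific granules. It lowered 9 of 27 immediate-early genes and raised 3, and it lowered 3 of 5 platelet markers. Ngp, which encodes a specific granule protein, rose from 61.0 ± 21.1 to 3730 ± 1380 CPM (SD, n = 3), and Chil3, a chitinase-like protein, from 4.93 ± 8.54 to 974 ± 213. Fos, a subunit of the AP-1 transcription factor, fell from 1340 ± 366 to 113 ± 68.9, and Csf3r from 5360 ± 396 to 1770 ± 377. In all, limma called 1095 genes, of which 630 rose and 465 fell, and 960 changed at least 2-fold. The groups did not overlap for 30.8% of all genes, where chance gives 10%.

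Among the largest rises in WT were Lipg, which encodes endothelial lipase, Chil3, the transcriptional regulator Id2 and Lgals3bp. Lipg (chromosome 18, 74939322 to 74961263) had 2 reads in saline and 1031 in LPS, a ratio of 512 with a 95% counting interval of 141 to 4230. Chil3 (chromosome 3, 106147554 to 106167564) rose by 8.52 ± 1.05 log2 units (adjusted p = 3.3e-06) and Id2 by 6.41 ± 0.79 (adjusted p = 3.11e-06). Lgals3bp had 0 reads in saline and 106 in LPS and was at least 11.5-fold higher (adjusted p = 7.7e-05). The other largest rises were of genes with opposite-strand overlap and are uncertain. Ikbke, a kinase of the interferon pathway, had 0 reads in saline and 935 in LPS and was at least 103-fold higher, with an overlap with Gm28914. Tmem198b rose by 6.34 ± 0.93 beside Mmp19, Rptor by 6.15 ± 0.86 beside Rptoros, and Ddx28 had a read ratio of 79.7 (27.0 to 389) beside Dus2. Among the largest falls, Clec9a, a dendritic cell receptor, had 174 reads in saline and 0 in LPS and was at least 18.8-fold lower (adjusted p = 3.8e-06). Fosb, with 91 and 0 reads, was at least 10.7-fold lower, Ptgfrn, with 65 and 0, at least 7.01-fold lower, and Foxq1, with 53 and 0, at least 5.9-fold lower, the last beside the antisense gene A530084C06Rik. Ttc21a changed by -5.72 ± 0.69, Ctc1, a telomere maintenance gene, by -4.95 ± 0.80, the sialyltransferase gene St8sia4 by -4.87 ± 0.67 and the stress-induced transcription factor gene Atf3 by -4.45 ± 0.91. All 16 of these genes kept their call without each library in turn.

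Of 38 measured interferon-stimulated genes, 23 rose in WT, none fell and 15 did not pass, and 28 rose when adjusted over the list alone. The list rose against all other genes (camera adjusted p = 1.13e-17; adjusted p = 0.0103 with an estimated correlation), and its level went from 5.23 ± 0.17 to 6.95 ± 0.23 (SD, n = 3). Ifit2 rose by 4.27 ± 0.76, the nucleic acid sensor gene Zbp1 by 3.71 ± 0.51, Ifit3 by 3.48 ± 0.44 and Gbp2, which overlaps Mir6381, by 3.38 ± 0.42. Of 18 specific granule genes, 13 rose, none fell and 5 did not pass, with 15 rising when adjusted over the list alone (camera adjusted p = 1.14e-14). For this list the adjusted p = 0.0806 with an estimated correlation. Beside Chil3 and Ngp (5.89 ± 0.55), Itgb2l rose by 4.73 ± 0.86, and Camp, the cathelicidin gene, had a read ratio of 35.2 (9.40 to 297). The list's level rose from 5.19 ± 0.14 to 7.91 ± 0.30. Of 8 azurophil granule genes, 3 rose and 5 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.092). Serpinb1a had a read ratio of 38.7 (10.4 to 325). Of 14 gelatinase and secretory vesicle genes, 5 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.232). The formyl peptide receptor genes Fpr1 and Fpr2 rose by 2.37 ± 0.35 and 2.35 ± 0.37 and the membrane metalloprotease gene Mmp25 by 2.0 ± 0.29, while Vnn3 changed by -3.84 ± 0.65.

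Of 27 immediate-early and MAP kinase genes, 9 fell, 3 rose and 15 did not pass in WT, and 11 fell and 3 rose when adjusted over the list alone. The list fell against other genes (camera adjusted p = 0.0397), with adjusted p = 0.705 with an estimated correlation. Fosb, Atf3 and Fos (-3.68 ± 0.59) fell, and the nuclear receptor gene Nr4a1 rose by 2.10 ± 0.41. Of 5 platelet markers, 3 fell, also when adjusted over the list alone, and 2 did not pass (camera adjusted p = 0.0474; adjusted p = 0.365 with an estimated correlation). Gp1ba, a subunit of the platelet von Willebrand factor receptor, changed by -1.64 ± 0.26, and Clec1b, with 32 and 0 reads, was at least 3.45-fold lower. The annotated spans of Clec1b (chromosome 6, 129397297 to 129409335) and Clec9a (129408862 to 129424763) overlap on the same strand. The platelet marker level went from 6.24 ± 0.38 to 4.58 ± 0.27. Of 23 NADPH oxidase and antioxidant genes, 5 rose and 18 did not pass, while 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0397; adjusted p = 0.365 with an estimated correlation). The oxidase subunit genes Cybb, Ncf4 and Cyba rose by 2.46 ± 0.54, 1.62 ± 0.27 and 1.12 ± 0.25, as did Ncf1 (1.41 ± 0.28), whose exons overlap Gtf2ird2. The immediate-early call was lost without each of WT-Saline replicates 1 and 2, WT-LPS replicates 2 and 3 and KO-Saline replicates 1, 2 and 3 (camera adjusted p up to 0.13), and the platelet call without each of WT-Saline replicates 2 and 3, WT-LPS replicates 1 and 2 and KO-Saline replicates 1, 2 and 3 (up to 0.109). The NADPH oxidase call was lost without each of WT-Saline replicates 2 and 3, WT-LPS replicate 3 and KO-Saline replicates 1 and 3 (up to 0.0951).

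The remaining lists did not pass in WT, although members of many of them changed. Among 30 NF-kB targets, cytokines and chemokines, 10 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.124). The gene of the anti-inflammatory cytokine Il10 rose by 5.0 ± 1.05, and Ptgs2, which encodes cyclooxygenase-2, changed by -3.83 ± 1.16, a call lost without each of WT-Saline replicates 1 and 2 and WT-LPS replicates 2 and 3 (adjusted p up to 0.169). Of 23 adhesion and chemoattractant receptor genes, 7 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.644), among them the leukotriene receptor gene Ltb4r1 at 2.36 ± 0.38. Of 18 inflammasome and cell death genes, 1 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.627). Nlrp3 changed by -1.87 ± 0.41, Il1b by -2.22 ± 0.42 beside its antisense gene Il1bos, and Naip5 rose by 3.57 ± 0.79. Of 26 genes of Toll-like receptor and HMGB1 receptor signalling, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.893). Irak3, a negative regulator of this pathway, rose by 1.86 ± 0.35 (overlap with Tmbim4) and the adaptor gene Traf6 changed by -2.79 ± 0.61. In the autophagy list 3 of 31 genes fell (3 adjusted over the list alone; camera adjusted p = 0.739), among them Atg3 at -1.72 ± 0.40. In the heat shock list 1 of 23 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.627), among them the chaperonin gene Hspd1 at -3.05 ± 0.64, whose exons overlap Hspe1. Of 26 glycolysis genes 3 rose and 2 fell, and of 12 lipid mediator genes 3 rose and 1 fell, each with the same counts adjusted over the list alone and a camera adjusted p = 0.627. Of 20 apoptosis genes 1 rose and 1 fell (camera adjusted p = 0.739). None of 10 high-mobility group genes, 9 cell cycle genes and 31 oxidative phosphorylation genes was called, also when adjusted over the list alone (camera adjusted p = 0.847, 0.966 and 0.739).

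Of 14 mature neutrophil markers, 5 rose and 3 fell in WT (6 and 4 adjusted over the list alone; camera adjusted p = 0.739). Ly6g, the antigen commonly used to identify mouse neutrophils, rose by 2.62 ± 0.48 and the decoy receptor gene Il1r2 by 1.68 ± 0.32, while Csf3r changed by -1.62 ± 0.30 and the chemokine receptor gene Cxcr4 by -2.33 ± 0.40. Markers of other blood cells also moved. Of 9 monocyte and macrophage markers, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.845), with Ly6c2 at 3.67 ± 0.45 and Apoe at -3.36 ± 0.73. Clec9a was the called member of 8 dendritic cell markers (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.845). Tcf7 at -3.17 ± 0.92 was the called member of 5 T and NK cell markers (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.739), and this call was lost without each WT-Saline replicate and without WT-LPS replicate 1 (adjusted p up to 0.13). The B cell, erythroid and eosinophil lists had 4, 3 and 2 measured members and were not tested. Of these, the B cell receptor gene Cd79a rose by 2.61 ± 0.55 and the others did not pass. Without a mean-variance trend the model called 363 genes in WT. Among the 77 called genes that the naming rule took, 56 kept their call without each library in turn, and 38 kept it under all other alternatives.

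The second comparison asked the same of the KO-labelled libraries. LPS again raised interferon-stimulated genes, 10 of 38, and 8 of 18 specific granule genes. Lcn2, which encodes the iron-scavenging granule protein lipocalin-2, rose from 588 ± 119 to 5220 ± 3780 CPM (SD, n = 3) and Ifit1 from 48.2 ± 31.6 to 201 ± 79.7. Nos2, the inducible nitric oxide synthase gene, rose from 6.12 ± 10.6 to 118 ± 67.2. In all 314 genes were called, of which 187 rose and 127 fell, and 277 changed at least 2-fold. The groups did not overlap for 17.6% of all genes, against 10% by chance. For some genes the spread within KO-LPS was large because replicate 1 lay near the saline libraries. Lcn2 had 325 reads in replicate 1 and 2933 and 3530 in replicates 2 and 3, Chil3 5 against 656 and 592, and Lipg 10 against 295 and 357. This did not hold for Ifit1, with 68 reads in replicate 1 and 117 and 62 in replicates 2 and 3. Without KO-LPS replicate 1 the model called 1076 genes.

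The calls that held without each library in turn were of Lipg (5.78 ± 0.91, adjusted p = 0.000824), Nos2 (5.11 ± 0.81, adjusted p = 0.000845), St8sia1 (5.12 ± 0.83, overlap with Gm7457), Lcn2 (2.64 ± 0.45, adjusted p = 0.00125), Nr4a1 (2.50 ± 0.41) and Ifit1 (2.21 ± 0.40, adjusted p = 0.00217) among rises, and Ctc1 (-4.49 ± 0.80, adjusted p = 0.00213), Anks6 (-2.95 ± 0.52) and the cystine transporter gene Slc7a11 (-2.70 ± 0.49) among falls. These were 9 of the 52 called genes that the naming rule took. Under the alternatives other than leaving out libraries, only 2 of the 52 kept their call throughout. Of the 43 that lost their call without some library, 42 lost it without KO-LPS replicate 2 and 36 without KO-LPS replicate 3. None lost it without KO-LPS replicate 1, and 17, 26 and 25 did without KO-Saline replicates 1, 2 and 3 (adjusted p up to 0.342). Fewer lost it without a WT library, at most 6. They included Chil3 at 5.54 ± 1.05, the prion protein gene Prnp, at least 7.49-fold higher, the secreted kinase gene Fam20c, with a read ratio of 50.3 (16.9 to 246), and the acute phase gene Saa3, at least 17.6-fold higher. Among falls they included Pde3b at -3.81 ± 0.97, Eef2k at -3.72 ± 0.90 beside Gm15774, Nat8l at -3.33 ± 0.94, Peak1 at -3.03 ± 0.63 beside Peak1os, the nicotinic acid receptor gene Hcar2 at -2.79 ± 0.67, and Btbd10, with 39 reads in saline and 3 in LPS, a ratio of 0.0773 (0.0153 to 0.243).

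Of the 38 interferon-stimulated genes, 10 rose in the KO-labelled libraries, none fell and 28 did not pass, and 16 rose when adjusted over the list alone (camera adjusted p = 1.83e-11; adjusted p = 0.0409 with an estimated correlation). The list level went from 5.27 ± 0.22 to 6.39 ± 0.19 (SD, n = 3). Ifit2 rose by 4.07 ± 0.76 and Zbp1 by 2.53 ± 0.51, both calls lost without KO-LPS replicate 2 (adjusted p = 0.0532 and 0.0883). Of the 18 specific granule genes, 8 rose and 10 did not pass, with 9 rising when adjusted over the list alone (camera adjusted p = 7.28e-10; adjusted p = 0.199 with an estimated correlation). Their level went from 5.87 ± 0.46 to 7.57 ± 0.93, with 6.49 in KO-LPS replicate 1. Ngp rose by 2.80 ± 0.55 and Itgb2l by 4.16 ± 0.86, both calls lost without each of KO-Saline replicate 3 and KO-LPS replicates 2 and 3 (adjusted p up to 0.0744 and 0.0846). Of 8 azurophil granule genes, 2 rose (3 rose and 1 fell adjusted over the list alone), the protease gene Ctsc at least 4.0-fold and Cst7 with a ratio of 45.2 (7.72 to 1830), both calls lost without KO-LPS replicate 2 or 3 and that of Cst7 also without KO-Saline replicate 2 (adjusted p up to 0.0846 and 0.132). This list rose against other genes (camera adjusted p = 0.0479; adjusted p = 0.199 with an estimated correlation), a call lost without each of the WT-LPS replicates, KO-Saline replicates 2 and 3 and KO-LPS replicates 1 and 3 (up to 0.207). Of the 27 immediate-early genes, 2 fell and 3 rose, and 10 fell and 3 rose when adjusted over the list alone (camera adjusted p = 0.0479; adjusted p = 0.846 with an estimated correlation). That call was lost without each of WT-LPS replicate 2, KO-Saline replicates 1 and 3 and KO-LPS replicates 2 and 3 (up to 0.445). Without KO-LPS replicate 1, 14 interferon-stimulated and 10 specific granule genes rose (camera adjusted p = 2.32e-07 and 1.67e-14; adjusted p = 0.131 and 0.0147 with an estimated correlation), and 11 immediate-early genes fell while 3 rose (camera adjusted p = 2.64e-05; adjusted p = 0.387 with an estimated correlation).

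Outside these lists, 3 NF-kB targets rose (5 rose and 1 fell adjusted over the list alone), among them Tnip1, an inhibitor of this pathway, at 1.99 ± 0.42, and Cd14, the LPS co-receptor gene, rose by 1.52 ± 0.33. Both lost their call without KO-LPS replicate 2 or 3, and Cd14 also without KO-Saline replicate 2 or 3 (adjusted p up to 0.108 and 0.0959). Gp1ba was the 1 called platelet marker, at -1.30 ± 0.26, with a platelet marker level of 6.34 in KO-LPS replicate 1 against 4.88 and 4.40 in replicates 2 and 3. Its call was lost without KO-LPS replicate 2 or 3 (adjusted p up to 0.0767). Csf3r changed by -1.24 ± 0.30, a call lost without each of the KO-Saline replicates and KO-LPS replicates 2 and 3 (adjusted p up to 0.208). No other list passed camera in the KO-labelled libraries (adjusted p = 0.173 or above). The number of called genes was 32 without KO-LPS replicate 2, 47 without replicate 3, and 206, 129 and 108 without KO-Saline replicates 1, 2 and 3. It was 82 with the KO-labelled groups alone, 16 without a mean-variance trend, 179 with a pseudocount of 0.1 and 904 with array weights, which gave KO-LPS replicate 1 the lowest weight of 0.387.

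**Figure D2:**
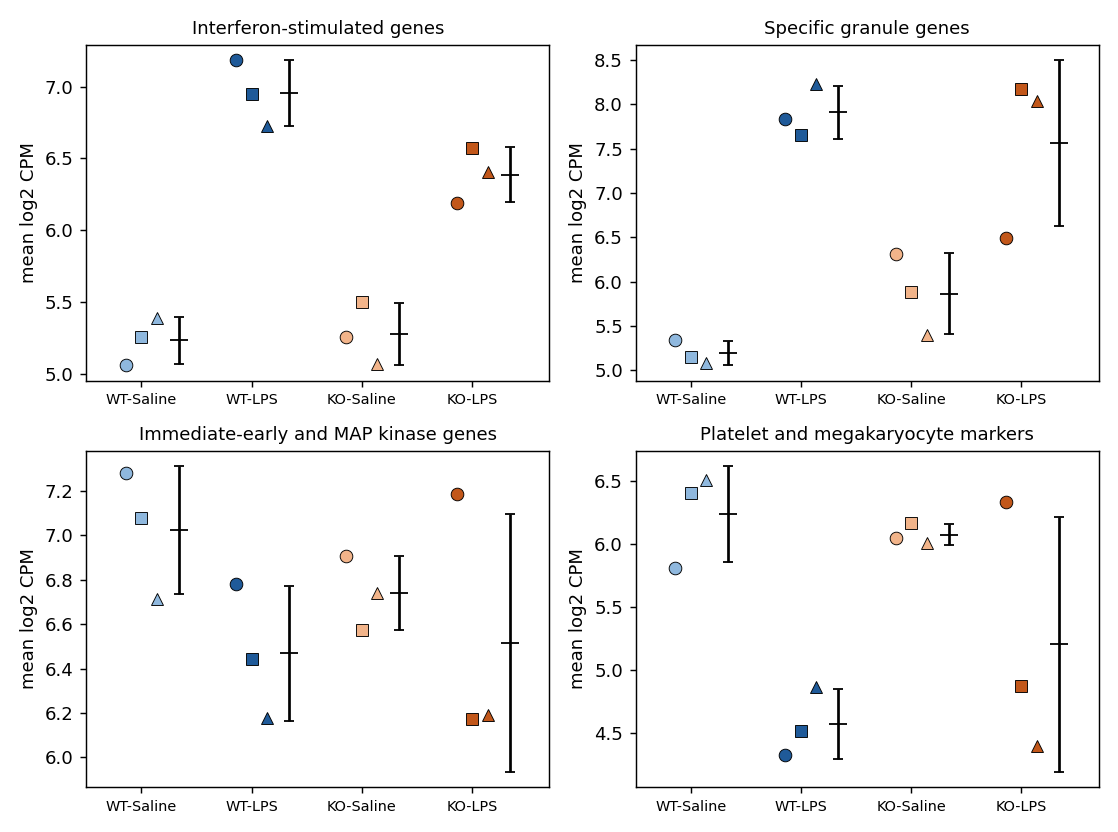
Mean log2 CPM (vertical axes) over the measured genes of 4 lists in each library of the 4 groups (horizontal axes), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). KO-LPS replicate 1 lies at 6.49 for specific granule genes, against 8.18 and 8.03 in replicates 2 and 3, and at 6.19 for interferon-stimulated genes, against at most 5.50 in the saline libraries.

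The responses of both genotypes shared their direction. Of the 1095 genes called in WT, 1052 (96.1%) had the same sign in the KO-labelled libraries, which share no library with the WT comparison. Both comparisons called 249 genes, all with the same sign: 142 rose in both, where 12.6 would by chance, and 107 fell in both, where 6.3 would. Across all 9374 genes the log2 fold changes correlated with Pearson's r = 0.518 and Spearman's rho = 0.473, a description across genes, which are not independent replicates. Over the genes called in WT, the slope of the KO-labelled on the WT fold changes was 0.546. Selecting these genes by their WT values inflates their WT fold changes, so a slope under 1 can also arise from equal responses. Without KO-LPS replicate 1, r was 0.59, the slope 0.752, the genes called in both 627 and the share with the same sign 98.0%. The WT and KO-labelled LPS responses were called at different numbers of genes, but no gene's response was called different by the interaction term described last.

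**Figure D3:**
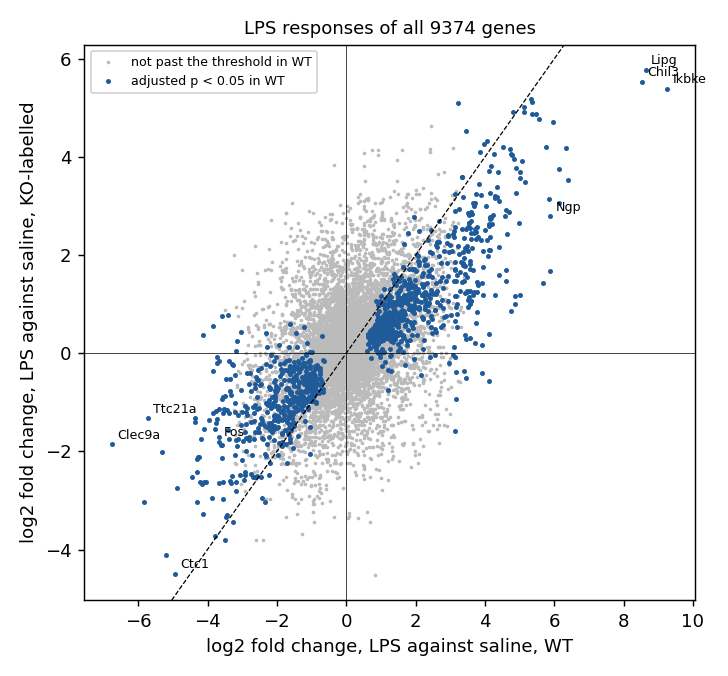
Log2 fold change of LPS against saline in WT (horizontal axis) and KO-labelled libraries (vertical axis) for all 9374 genes, fitted with 0.5 reads added, with a dashed line at equal changes and the genes not called in WT in grey. Of the 1095 genes called in WT (blue), 96.1% have the same sign on both axes.

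The third comparison asked what differed between genotypes without LPS. In saline the KO-labelled libraries had less Ecm1, which encodes an extracellular matrix glycoprotein. Specific granule genes were higher as a group, but with no single member called and not with an estimated correlation (adjusted p = 0.398). Ecm1 (chromosome 3, 95734147 to 95739569, minus strand) was the 1 gene called, at 34.4 ± 1.98 CPM against 156 ± 46.6 in WT (SD, n = 3), a log2 difference of -2.11 ± 0.33 (adjusted p = 0.00715). Its reads were 13, 15 and 15 in KO-Saline and 63, 53 and 110 in WT-Saline. The 18 specific granule genes were higher as a list (camera adjusted p = 0.000294; adjusted p = 0.398 with an estimated correlation), with a level of 5.87 ± 0.46 against 5.19 ± 0.14, although none was called over all genes and 4 rose when adjusted over the list alone. The difference of 0.67 in level had an exact permutation p of 0.1, the smallest that 3 against 3 can give. Their most abundant members Hp and Lcn2 had log2 differences of 0.12 ± 0.20 and 0.62 ± 0.45 (adjusted p = 0.964 and 0.858). The NADPH oxidase, mature neutrophil and gelatinase lists were also higher (camera adjusted p = 0.0246, 0.036 and 0.0433; adjusted p = 0.398 for each with an estimated correlation). Of their members, 0, 1 and 0 passed when adjusted over the list alone.

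Next to Ecm1 stood genes of small p that did not pass in saline. Hspd1 differed by -3.33 ± 0.64 (adjusted p = 0.0766, overlap with Hspe1). The adaptor gene Sla differed by 1.75 ± 0.36, the casein kinase gene Csnk1d by -1.49 ± 0.31 (overlap with Gm28192) and Adamtsl4 by -1.02 ± 0.22, each with adjusted p = 0.0951. Gpr27, also at 0.0951, had 1 read in WT-Saline and 29 in KO-Saline, a ratio of 32.9 (5.46 to 1350). All 5 passed without KO-LPS replicate 1, Hspd1 also without WT-LPS replicate 1 or KO-LPS replicate 2, and Sla also without KO-LPS replicate 3. The LPS libraries are not part of the saline difference and act on it only through the estimate of the spread that all 12 libraries share. The count of 1 called gene thus depends on the spread within the LPS groups too. The unadjusted p was under 0.05 for 643 genes, and the groups did not overlap for 13% of genes, against 10% by chance. The Ecm1 call was lost without each of WT-Saline replicates 1 and 3 and KO-Saline replicates 1 and 2 (adjusted p up to 0.0995), and without a trend or with voom weights, its adjusted p over all alternatives running from 3.08e-05 to 0.394. The count of called genes was 0 without each of WT-Saline replicate 1 and KO-Saline replicates 1 and 2 and without a trend, 2 without each of WT-Saline replicate 3 and KO-LPS replicates 2 and 3, 3 without each of WT-LPS replicate 1 and KO-Saline replicate 3, 31 without KO-LPS replicate 1, 4 with a pseudocount of 5, 2 with voom weights, 17 with array weights and 22 with the saline groups alone. The specific granule call held without each library in turn, and the other 3 list calls were each lost without WT-Saline replicate 2, KO-Saline replicate 1 or KO-Saline replicate 3, the mature neutrophil call also without WT-Saline replicate 1 (camera adjusted p up to 0.338, 0.447 and 0.609 for the NADPH oxidase, mature neutrophil and gelatinase lists).

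The fourth comparison asked what differed between genotypes under LPS. Interferon-stimulated genes were lower as a group in the KO-labelled libraries, and no single gene was called. The list of 38 genes was lower against all other genes (camera adjusted p = 2.6e-08; adjusted p = 0.104 with an estimated correlation), with a level of 6.39 ± 0.19 against 6.95 ± 0.23 in WT-LPS (SD, n = 3). All 3 KO-LPS libraries lay below all 3 WT-LPS libraries, and the difference of -0.57 had an exact permutation p of 0.1, the smallest possible. Adjusted over the 23 tested lists, this exact permutation p was 0.92. With 3 libraries against 3 no list could pass after this adjustment, so the test cannot decide whether the separation is chance among the lists. In saline the levels were 5.27 ± 0.22 and 5.23 ± 0.17 (exact permutation p = 0.7). No member was called, also when adjusted over the list alone. The most abundant members were Oas3, a sensor of double-stranded RNA, at 594 ± 23.1 against 821 ± 57.0 CPM (log2 difference -0.47 ± 0.20, adjusted p = 0.949), and Oasl2, with a log2 difference of -0.05 ± 0.25 (adjusted p = 0.996). The list call held without each library in turn, and without KO-LPS replicate 1 its adjusted p was 1.9e-07 (adjusted p = 0.232 with an estimated correlation). Specific granule levels were 7.57 ± 0.93 in KO-LPS and 7.91 ± 0.30 in WT-LPS (exact permutation p = 0.8), and KO-LPS replicate 1 set the direction: without it the KO-LPS level was 8.10 and the difference turned from -0.34 to 0.20. With all libraries no other list passed camera (adjusted p = 0.137 or above). Lists passed without single libraries: immediate-early genes as lower without KO-LPS replicate 1 (camera adjusted p = 0.005; adjusted p = 0.979 with an estimated correlation), specific granule genes as lower without KO-LPS replicate 2 or 3 (0.00112 and 0.00506; adjusted p = 0.723 and 0.724 with an estimated correlation) and platelet markers as higher without KO-LPS replicate 3 (0.02; adjusted p = 0.584 with an estimated correlation).

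Limma called 0 genes between genotypes under LPS, with 471 at an unadjusted p under 0.05, and groups that did not overlap for 10.1% of genes against 10% by chance. Voom weights called 1 gene. Without WT-LPS replicate 2 the model called 2 genes, and without KO-LPS replicate 2 it called 1. The smallest p-values, none of which passed (adjusted p = 0.53), belonged to the magnesium transport gene Cnnm2 at 1.89 ± 0.42, the retinoic acid receptor gene Rarg at -1.74 ± 0.39 and Ttc21a at 2.83 ± 0.69, and to Clec9a and Ptgfrn, both with 0 reads in WT-LPS. Several of these differences rested on KO-LPS replicate 1, the library near saline. In KO-LPS replicates 1, 2 and 3, Clec9a had 21, 2 and 2 reads, Ptgfrn 7, 2 and 5, Ttc21a 68, 12 and 11, and Rarg 59, 341 and 385. Without replicate 1 the difference was -0.94 for Rarg and 1.92 for Ttc21a, and the few Clec9a reads left set no bound. Without WT-LPS replicate 2 the Ttc21a difference was 4.04 and passed (adjusted p = 0.00171).

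Averaged over both treatments, Ecm1 was the 1 gene called between genotypes, at -1.41 ± 0.24 (adjusted p = 0.0171), with 153 ± 61.6 CPM in KO-LPS and 245 ± 60.5 in WT-LPS (SD, n = 3). The unadjusted p was under 0.05 for 530 genes. The genes of next smallest p did not pass: Gm20319 at 0.90 ± 0.18 (overlap with Il1rap) and Wfdc17, which encodes a secreted protein of activated macrophages, at 1.28 ± 0.27, both with adjusted p = 0.146, Nol4l at 1.03 ± 0.24 and Gm10791 at 0.88 ± 0.20 (adjusted p = 0.302), and Sipa1l1 at 1.13 ± 0.27 (adjusted p = 0.416). Gm20319 and Nol4l passed without WT-LPS replicate 2 or KO-LPS replicate 1, Wfdc17 without KO-LPS replicate 1 and Gm10791 without WT-LPS replicate 2. Interferon-stimulated genes were lower as a list (camera adjusted p = 0.00538; adjusted p = 0.619 with an estimated correlation), with 2 members lower when adjusted over the list alone. This list call was lost without WT-Saline replicate 3 or WT-LPS replicate 1 (up to 0.0807). Without KO-LPS replicate 1, specific granule and gelatinase genes also passed, as higher (camera adjusted p = 2.18e-06 and 0.0206; adjusted p = 0.143 and 0.506 with an estimated correlation), and immediate-early genes, as lower (0.00603; adjusted p = 0.506 with an estimated correlation). Mature neutrophil markers passed as higher without each of WT-Saline replicate 3, WT-LPS replicate 2 and KO-LPS replicate 2 (0.015, 0.0215 and 0.00765; adjusted p = 0.595, 0.658 and 0.515 with an estimated correlation). The Ecm1 call was lost without each of WT-Saline replicates 1 and 3, WT-LPS replicate 1 and KO-Saline replicates 1, 2 and 3 (adjusted p up to 0.129), and without a trend or with voom weights (range over all alternatives 0.00483 to 0.325). The count was 0 without a trend and without each of WT-Saline replicate 1, WT-LPS replicate 1 and KO-Saline replicates 1, 2 and 3, 3 with array weights, 4 without WT-LPS replicate 2 and 11 without KO-LPS replicate 1.

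The interaction asked whether the LPS response differed between genotypes. The responses of interferon-stimulated and specific granule genes were smaller as groups in the KO-labelled libraries (camera adjusted p = 3.59e-05 and 3.52e-05; adjusted p = 0.366 for both with an estimated correlation). The interferon-stimulated level rose by 1.11 with LPS in KO-labelled and by 1.72 in WT libraries, and the specific granule level by 1.70 and 2.71. Without KO-LPS replicate 1 the KO-labelled rises were 1.21 and 2.24 and the list calls stood at adjusted p = 0.000209 and 0.0117 (adjusted p = 0.4 for both with an estimated correlation). Both list calls held without each library in turn. The specific granule level was already higher in KO-Saline than in WT-Saline (5.87 against 5.19). Without KO-LPS replicate 1 it was also higher in KO-LPS than in WT-LPS (8.10 against 7.91). When adjusted over the list alone, 2 specific granule genes and no interferon-stimulated gene passed, in both cases 0 over all genes. NADPH oxidase and antioxidant genes also passed (camera adjusted p = 0.0355; adjusted p = 0.366 with an estimated correlation), a call lost without each of WT-Saline replicates 2 and 3, WT-LPS replicate 3, KO-Saline replicates 1 and 3 and KO-LPS replicates 1 and 2 (up to 0.211). No list passed the rotation test fry in this comparison or in any of the 3 between genotypes.

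Limma called 0 genes for the interaction, with 560 at an unadjusted p under 0.05. Array weights called 4 genes and voom weights 2. The count was 1 without WT-LPS replicate 2 and 3, 7 and 6 without KO-LPS replicates 1, 2 and 3. Among the smallest p-values were those of Csnk1d at 2.13 ± 0.44 beside Gm28192, with adjusted p = 0.226, and of Ttc21a at 4.39 ± 0.97, the splicing gene Smu1 at 1.95 ± 0.44 (overlap with Dnaja1) and Zswim4 at 2.02 ± 0.47, each with adjusted p = 0.272. None of them passed with all libraries. Csnk1d passed without each KO-LPS replicate in turn, Ttc21a without WT-LPS replicate 2 or KO-LPS replicate 3, and Zswim4 without KO-LPS replicate 3. Ttc21a fell in WT from 385 ± 39.8 to 14.1 ± 20.7 CPM (SD, n = 3) and stood at 138 ± 56.0 and 78.2 ± 89.4 in KO-Saline and KO-LPS.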

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

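The tests of explanations and of other groupings in this part were chosen after the results were seen. The list tests of the interaction were planned. A test of the difference itself marked 3 gene lists whose LPS response differed between genotypes: interferon-stimulated genes (camera adjusted p = 3.59e-05), specific granule genes (3.52e-05) and NADPH oxidase genes (0.0355), none of which held with an estimated correlation (adjusted p = 0.366). All 3 responses were smaller in the KO-labelled libraries. For specific granule and NADPH oxidase genes the level was already higher in KO-Saline than in WT-Saline (5.87 against 5.19 and 6.06 against 5.65). Without KO-LPS replicate 1 both levels were also higher in KO-LPS than in WT-LPS (8.10 against 7.91 and 6.43 against 6.34). For these lists a weaker rise therefore cannot be told apart from a higher saline level. Single libraries were not tested against the rest of their group of 3 by a fixed rule, but array weights, estimated over all genes, were lowest for KO-LPS replicate 1 (0.387).

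KO-LPS replicate 1 lay near the saline libraries for most LPS-responsive genes. Measured from the mean of the KO-Saline libraries, it reached 0.135 of the WT response over the 1095 genes called in WT. KO-LPS replicates 2 and 3 reached 0.765 and 0.738. The KO-Saline libraries, at -0.058 to 0.092, average out by construction, so only their spread is informative. Selecting the genes by their WT response inflates that response and lowers the shares. The tables argue against a saline library with a wrong label, since its interferon-stimulated level exceeded that of the highest of the 6 saline libraries by 0.69, against an SD of 0.174 among those 6. They also argue against saline and LPS RNA mixed in a single proportion, for these genes. Its median share of the KO-labelled response was 0.599 over 23 interferon-stimulated genes (quartiles 0.377 to 1.08). Over 13 specific granule genes it was 0.017 (0.005 to 0.078), a difference of 0.582 (permutation over genes, p = 0.0245 with 100000 resamples). Genes within a library are not independent replicates, so this p does not measure the spread between libraries. What stays open, and was not tested, is a weaker or differently timed exposure or a biological difference between samples.

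Genes that overlap exons on the opposite strand held many of the reads. Long non-coding RNAs had more reads than the protein-coding gene on the other strand in 75% of 224 pairs (95% interval 68.8% to 80.5%), against 41.5% when 182 long non-coding RNAs without overlap were set against random coding genes. Gm15441 had 7975.3 reads per library and its partner Txnip, an abundant transcript in many cells, 387.4. The same 75% argues against counting without strand, where the coding gene would also collect its other exons. It is what a stranded library counted with the opposite strand setting would give, which is a candidate explanation that may apply to all values here, Hmgb1 included. Values given for genes with opposite-strand overlap, among them Ikbke, Ddx28, Rptor, Csnk1d and Hspd1, may then be those of the overlapping gene, and those of other genes would come from the minor reads of the other strand. It may also be why known neutrophil genes such as S100a8 rank below unfamiliar ones. No biological explanation was tested.

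In saline, the difference of the KO-labelled from the WT libraries went with the WT LPS response across genes, for the greater part as the shared WT-Saline libraries alone would give. Across genes the covariance of this difference with the WT response was 0.435, of which the shared WT-Saline libraries alone would give 0.322, with a simulated value of 0.321, and r was 0.389 against a simulated 0.499. The part left over was 0.113 (jackknife SE 0.049), and 0.072 to 0.144 without single libraries, while simulated unchanged genes, drawn independently, left -0.002 (SD 0.014). It lies more than 2 SE above 0, but with groups of 3 its 95% interval (t with 4 degrees of freedom) runs from -0.022 to 0.248, so chance values shared through the controls cannot be told apart from a real shift. Without KO-Saline replicate 1 the left over part was 0.072, which keeps open that this library alone may be the cause. The real grouping gave the highest left over covariance, the next being 0.056, but 10 groupings are too few for a share under 0.05, and an effect of the genotype stays among the open explanations.

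Other groupings of the 6 libraries were refitted for each pairwise comparison, and 10 groupings are too few for a share under 0.05. LPS against saline called 1095 genes in WT against at most 0 in another grouping, and 314 in KO-labelled libraries against at most 108. KO-labelled against WT called 1 gene in saline, as many as in 1 other grouping, 2 of the 10 in all. Under LPS it called 0, the highest other grouping 3, and since a count of 0 is reached by each of the 10 groupings by construction, this comparison says nothing about chance. For both LPS responses the real grouping was the 1 of 10 with the most calls. Of 100 groupings of the 12 libraries, 7 called as many genes as the averaged genotype difference (1, highest other 6), so chance cannot be excluded for it. The interaction called 0 genes (highest other 2), which all 100 groupings reach by construction, so for it they say nothing.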

How the results depend on the processing

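Voom weights, genes without opposite-strand overlap, and leaving out libraries for lists, Hmgb1 and the correlation were chosen after seeing the data. Leaving out the low-value filter changed nothing, since it removed no gene, and the alternatives planned for raw counts were not run because the table holds log2 values. In the LPS response of WT, 1095 genes became 363 without a trend, 624 among genes without opposite-strand overlap, where fewer genes were tested, 1433 with its groups alone and 734 to 1427 without single libraries. In KO-labelled libraries, 314 became 179 with a pseudocount of 0.1, 16 without a trend, 904 with array weights, 186 among genes without overlap, 82 with its groups alone and 32 to 1076 without single libraries. Between genotypes in saline, 1 became 4 with a pseudocount of 5, 0 without a trend, 17 with array weights, 2 with voom weights, 22 with its groups alone and 0 to 31 without single libraries. Under LPS, 0 became 1 with voom weights and 0 to 2 without single libraries. The averaged difference went from 1 to 0 without a trend, 3 with array weights and 0 to 11 without single libraries. The interaction went from 0 to 4 with array weights, 2 with voom weights and 0 to 7 without single libraries. Lists passing camera were 5, 4, 4, 1, 1 and 3 in these 6 comparisons, in this order. With an estimated correlation they were 1, 1, 0, 0, 0 and 0. Fry in a single direction, which does not compare a list with other genes, gave 8 in WT, 3 in KO-labelled libraries and 0 in the other 4 comparisons, and fry in either direction 21, 13 and 0. Without single libraries the camera counts ran from 2 to 5, 2 to 4, 1 to 4, 1 to 3, 0 to 4 and 2 to 3. The correlation of both LPS responses went from 0.518 to 0.63 with a mean of at least 10 and to 0.417 to 0.59 without single libraries. Libraries outside the 2 groups of a pairwise comparison act on its gene count only through the shared estimate of the spread. Except where the construction is named, the cause was not tested.

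The replicate numbers share no day or animal in the labels, and libraries of the same number did not deviate together (correlations -0.066 to 0.04 over 18 pairs, against -0.064 to 0.052 over 36 pairs of different numbers). With the replicate number as a block the averaged difference called 2 genes, the LPS response 1086 in WT and 336 in KO-labelled libraries, and the other counts were 1, 0 and 0. Quantile normalization moved the median log2 fold change of all genes in the KO-labelled response from 0.09 to -0.01. Among 379 results on named genes under all alternatives, 7990 of 8475 values kept their side of the threshold, 432 lost it, 53 gained it and none changed sign while called. Most of these results were not called to begin with, so the total overstates how stable the calls were. Of the 432 losses, 280 were in the KO-labelled LPS response, with 52 called named genes, and 138 in that of WT, with 77. The averaged Hmgb1 difference of 0.16 passed under no alternative. The simulation, run at a single depth, spread and group size, recovered 2-fold changes in 1.4% of genes.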

Other observations

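The observations in this part were chosen after the data were seen and come with no explanation. Ecm1, the 1 gene called between genotypes in saline, and Adamtsl4, among the 5 genes of next smallest p there, are near each other on the minus strand of chromosome 3, Adamtsl4 at 95676201 to 95687917 and Ecm1 at 95734147 to 95739569. Both were lower in KO-Saline than in WT-Saline, Adamtsl4 at 697 ± 60.1 against 1420 ± 211 CPM (SD, n = 3), without passing (adjusted p = 0.0951). Under LPS Adamtsl4 stood at 895 ± 115 in KO-labelled and 881 ± 218 in WT libraries, while Ecm1 stood at 153 ± 61.6 and 245 ± 60.5.

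For the adaptor gene Sla and the chaperonin gene Hspd1, the mean of KO-Saline lay nearer to those of both LPS groups than the mean of WT-Saline did, without passing between genotypes. Both genes were taken from those of smallest p between the saline groups. An extreme level in the WT-Saline libraries alone would therefore give this pattern, and it does not show a shift in KO-Saline. Sla had 103 ± 28.2 CPM in WT-Saline, 350 ± 98.5 in KO-Saline, 393 ± 60.3 in WT-LPS and 379 ± 237 in KO-LPS (SD, n = 3). Its reads were 174, 121 and 136 in KO-Saline and 48, 167 and 279 in KO-LPS, replicates 1 to 3 in each. KO-LPS replicate 1 thus lowered the KO-LPS mean of Sla. Hspd1, which overlaps Hspe1, had 147 ± 75.3 in WT-Saline, 12.6 ± 4.06 in KO-Saline, 16.7 ± 9.83 in WT-LPS and 19.6 ± 12.3 in KO-LPS.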
